A study of Homo sapiens with 12 samples.

How the data were processed

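The series measured total RNA of HCT116 cells on NimbleGen expression arrays, 1 sample and 1 dye (Cy3) per array. The labels place 12 arrays in 3 groups, control, Tip60 and p400 siRNA, with 2 siRNAs per group and 2 cultures, A and B, per siRNA. Per the labels, cells were grown in DMEM with serum, RNA was purified on columns with DNase treatment, and its amount and integrity were checked before labelling. The deposited table holds log2 values, for which the authors list RMA as the processing tool. Its version, its settings and whether it summarised probes per transcript are not given in the sources used here. The scale was read from the values, which ran from 3.76 to 15.68. That table was the starting point, and no raw image or intensity file was used here.

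The table held 45033 features. A gene symbol was given to 18188 of them, and 0 features had several symbols; the other 26845 were kept apart and tested separately. The named features stand for 16583 genes, of which 1286 had several features; each gene was represented by the feature with the highest mean over the 12 arrays. Arrays have no read depth, so the level of the 387 odorant and taste receptor genes was used to show the background: their median was 5.40 and their 95th percentile 7.72, against a median of 9.57 over all genes. No gene was filtered out in the main analysis. All 66 pairs of arrays were checked for identical values.

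Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 3 group means was fitted to all 12 arrays, with empirical Bayes moderation of the variances. The contrasts were Tip60 against control, p400 against control and Tip60 against p400. P-values were adjusted over all 16583 genes by the Benjamini-Hochberg method, at a threshold of 0.05. A second model with 6 siRNA means served to compare the siRNAs of a group with each other and each siRNA with the mean of both control siRNAs. KAT5 and EP400, the targeted genes, were also tested by exact permutation of the 8 arrays, whose smallest two-sided p is 0.0286. Arrays, not siRNAs, are the unit of these tests.

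The 26 gene lists, with 589 members of which 541 were measured, were written before the data were examined, and so were the comparisons, tests, thresholds, alternatives (but 1, below) and the rule for naming genes. By that rule the text names KAT5 and EP400, the 10 genes with the largest rises and the 10 with the largest falls among those that passed the threshold, had no overlap between the arrays of the groups and moved the same way with both siRNAs, and up to 4 members of each list with the smallest adjusted p. For siRNA 1 against siRNA 2 it names the 5 genes with the smallest adjusted p, and for the overlap the 5 with the largest shared change. Genes whose groups did not overlap made up 9.10%, 21.3% and 9.22% of all genes in the 3 comparisons, against 2.86% by chance. Genes named beyond the rule were chosen after their values were seen: further members counted in a list, and those so described in the text. Lists were tested with limma's camera, with a preset correlation between genes of 0.01, and also with a correlation estimated from the data and with fry. List p-values were adjusted over the 26 lists. Members of a list were also adjusted over the list alone.

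Since both knockdowns are compared with the same control arrays, their overlap was set against 100 simulated draws of unchanged groups with shared controls, and recomputed with the control arrays split between the comparisons. The 2 siRNAs of a target were compared with separate control siRNAs. All 35 splits of 8 arrays into 4 and 4 were counted for the gene and list tests, and 100 drawn splits of the 12 arrays for the overlap.

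Alternatives tried were centring each array on its median, a further quantile normalization, leaving out the lowest 30% of genes, every feature on its own, the mean of a gene's features, trended and robust moderation, array weights, a fit to the 2 groups compared, culture letter or replicate label as a block, siRNA as a random block, 6 siRNA means, leaving out each siRNA or each array, and a log2 change of at least 1. Leaving out Control 2_A and Tip60 2_B together was chosen after seeing the data.

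The calling of genes was tested on simulated data drawn from the mean and spread of each gene, independent between genes, with 200 genes changed by a log2 of 0.5 or 1. The simulated arrays held no siRNA effects and no arrays that stood apart. In the Tip60 comparison it recovered 39% and 82% of them, with 13 false calls among 134. In the p400 comparison it recovered 53% and 86%, with 15 false calls among 154.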

Results

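HCT116 is a human colon carcinoma cell line with a mutant beta-catenin and intact p53. Total RNA of HCT116 cells was measured on 12 one-colour NimbleGen expression arrays. The arrays form 3 groups of 4: cells transfected with control siRNA, with siRNA against Tip60, or with siRNA against p400. Tip60 is a lysine acetyltransferase encoded by KAT5, and p400 is a SWI2/SNF2-type ATPase encoded by EP400. Both are subunits of the TIP60-p400 chromatin remodelling complex, which acetylates histones and exchanges H2A.Z. Each group holds 2 siRNAs, numbered 1 and 2, and each siRNA was used in 2 independent cultures, A and B. An array is named here by its group, siRNA number and culture, so that Control 2_A is culture A of control siRNA 2. The median of the deposited log2 values lay between 9.21 and 9.27 in each array. A total of 16583 named genes were tested. In the main fit to group means, limma p-values rest on the spread between the arrays of a group. That spread holds differences between the 2 siRNAs of the group as well as between cultures. In the fit with a mean for each siRNA, they rest on the spread between cultures of the same siRNA. The 387 odorant and taste receptor genes, for which a colon carcinoma line has no known use, served as a guide to the background. Their 95th percentile was 7.72, and 5996 genes had a mean below it.

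The arrays Control 2_A and Tip60 2_B stood apart from the other 10. They lay at -30.1 and -40.7 on the first principal component, which held 28.8% of the variance, while the other arrays lay between 2.03 and 13.6. The second component placed the 4 p400 arrays and both Tip60 siRNA 2 arrays between 9.78 and 17.9. It placed the control arrays and both Tip60 siRNA 1 arrays between -18.3 and -8.45. None of the 66 pairs of arrays held identical values.

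The targeted genes were examined first. With Tip60 siRNA, KAT5 fell from 12.59 ± 0.01 to 11.19 ± 0.87 (mean ± SD of log2 values, n = 4 each) in every Tip60 array, which left 37.9% of the control level (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays allow). The siRNAs differed in strength: KAT5 was at 63.6% of the control level with Tip60 siRNA 1 and at 22.6% with siRNA 2, a difference of 1.49 ± 0.08 (log2, SE; limma adjusted p = 0.000279). Because of that spread, the limma test on the 3 group means gave a log2 change of -1.40 ± 0.32 (SE) and missed the threshold (adjusted p = 0.0645). With the 6 siRNA means fitted separately, the same change passed it (limma adjusted p = 8.85e-05). A second KAT5 feature gave -1.42 ± 0.32. EP400 fell with p400 siRNA from 10.72 ± 0.25 to 9.48 ± 0.24, to 42.3% of the control level (log2 change -1.24 ± 0.15, limma adjusted p = 0.00841, exact p = 0.0286). It was at 48.3% with p400 siRNA 1 and at 37.0% with p400 siRNA 2. EP400 did not pass the test in Tip60 cells (log2 change 0.06 ± 0.15, limma adjusted p = 0.886), nor did KAT5 in p400 cells (-0.10 ± 0.32, adjusted p = 0.895).

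**Figure D1:**
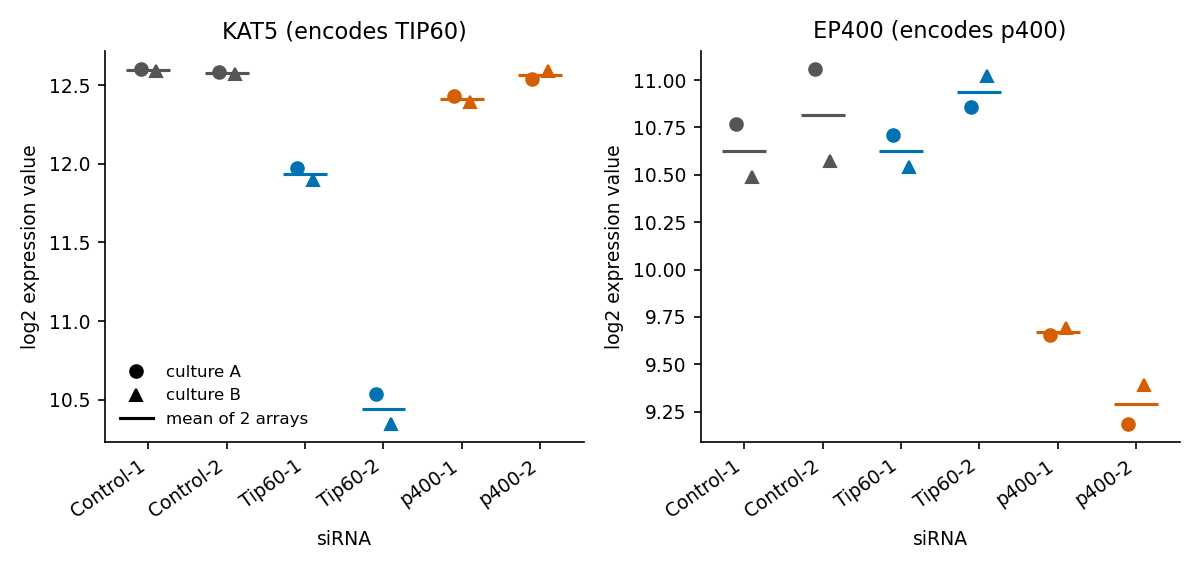
Log2 expression value of KAT5 (left) and EP400 (right) on each of the 12 arrays, by siRNA, with circles for culture A, triangles for culture B and a line at the mean of each siRNA's 2 arrays. KAT5 lay at 63.6% and 22.6% of the control level with Tip60 siRNA 1 and 2, and EP400 at 48.3% and 37.0% with p400 siRNA 1 and 2.

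The comparison of Tip60 siRNA with control siRNA asked which genes depend on Tip60 in these cells. HLA-DRA, a chain of MHC class II, rose by 1.10 ± 0.16 (log2, SE; n = 4 against 4; limma adjusted p = 0.0247), a 2.15-fold increase. Its mean over all arrays (7.82) lay only just above the 95th percentile of the receptor genes (7.72). ANGPT2, a ligand of the TIE2 receptor, rose 1.92-fold (0.94 ± 0.15, limma adjusted p = 0.0247), and the transcription factor gene KLF2 rose 1.70-fold (0.77 ± 0.15, adjusted p = 0.0386). Among the genes that fell were the glycine transporter gene SLC6A9 (-0.86 ± 0.16), DACT1, which encodes a regulator of Wnt signalling (-0.86 ± 0.15), the quinone reductase gene CRYZ (-0.69 ± 0.11) and the keratin gene KRT24 (-0.69 ± 0.13). The other genes with the largest rises were RGS5, OR2A12, ARMH4, HOXD3, HAVCR1, IGIP and CERKL, from 1.67-fold to 1.88-fold. Those with the largest falls were IL21R, HTR1E, GCGR, ADCY8, CFHR2 and CAPN11, from 1.66-fold to 1.90-fold. All 13 had means below the 95th percentile of the receptor genes, ARMH4 the closest to it (7.65 against 7.72).

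In total 160 genes passed limma's test at an adjusted p of 0.05, 73 higher and 87 lower with Tip60 siRNA, and 2795 had an unadjusted p under 0.05. Of the 160, 81 also passed with each Tip60 siRNA taken alone, a count that was between 0 (without Tip60 1_A) and 43 (without Control 2_A) when any 1 of the 12 arrays was left out. HLA-DRA was the 1 gene past the threshold that changed at least 2-fold, and 42 of the higher and 23 of the lower genes had means below the receptor-gene percentile. The count changed with the loss of 1 array. It was between 14 (without Control 2_B) and 61 (without Tip60 1_A) when any array other than Control 2_A or Tip60 2_B was left out. That range includes leaving out a p400 array, which is not in this comparison but adds to the shared estimate of the spread. The lower counts therefore need not come from the values of single Tip60 or control arrays. With siRNA as a random block limma called 0 genes (2002 with an unadjusted p under 0.05). That fit still uses all arrays, and allows for a correlation between the cultures of a siRNA (0.235).

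Of the 26 gene lists chosen before the data were examined, 5 passed limma's camera test with a preset correlation between genes. Cholesterol synthesis stood out: all 19 measured genes lay lower with Tip60 siRNA, with a median log2 change of -0.21 (camera adjusted p = 2.72e-07; adjusted p = 0.406 with an estimated correlation). TM7SF2, a sterol reductase gene (-0.31 ± 0.05), and SREBF2, which encodes the transcription factor that drives the pathway (-0.37 ± 0.07), fell, and 17 genes did not pass over all genes tested. Adjusted over the list alone, 4 fell. The median of the list was -0.10 with Tip60 siRNA 1 and -0.29 with siRNA 2. In hypoxia and glycolysis, P4HA1 (-0.34 ± 0.06), PFKFB4 (-0.50 ± 0.10) and ALDOC (-0.39 ± 0.08) fell of 19 genes, 3 adjusted over the list alone (list median -0.07, camera adjusted p = 0.0292; adjusted p = 0.406 with an estimated correlation). They encode a collagen prolyl hydroxylase, a regulator and an enzyme of glycolysis. Of 24 Wnt/beta-catenin targets, DKK1, a secreted Wnt antagonist, rose (0.39 ± 0.07), 1 also adjusted over the list alone (list median 0.15, camera adjusted p = 0.0106; adjusted p = 0.406 with an estimated correlation). The list's median was 0.04 with Tip60 siRNA 1 and 0.31 with siRNA 2. No member of 23 replication-dependent histone genes (median 0.26, camera adjusted p = 0.0106; adjusted p = 0.862 with an estimated correlation) or of 16 epithelial genes (median -0.09, camera adjusted p = 0.0292; adjusted p = 0.406 with an estimated correlation) passed limma's test, over all genes or adjusted over the list alone. Leaving out 1 array ended the hypoxia call (adjusted p = 0.116 without Control 1_A, 0.0656 without Tip60 1_B, 0.134 without Tip60 2_B) and the histone call (0.226 without Tip60 2_B, and 0.692 with a median of 0.04 instead of 0.26 without Control 1_A, whose histone mean lay at -0.61 from the control mean). It also ended the epithelial call (0.137 without Control 1_A, 0.0687 without Tip60 1_A, 0.109 without Tip60 1_B) and the Wnt call (0.0507 without Tip60 2_A). Without Tip60 siRNA 1 the hypoxia (0.168), histone (0.0509) and epithelial (0.498) calls ended, and without Tip60 siRNA 2 the hypoxia (0.111), histone (0.128) and Wnt (0.376) calls did. Without control siRNA 1 the hypoxia (0.174, median -0.02), histone (0.260) and epithelial (0.231) calls ended, and without control siRNA 2 the Wnt call did (0.0597). The epithelial call also ended with 6 siRNA means (0.0557), and the histone (0.219), hypoxia and Wnt calls (0.0515 each) with array weights.

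The other 21 lists had camera adjusted p-values between 0.152 (ATF4 and unfolded protein response) and 0.862 (mesenchymal and fibroblast markers) in this comparison. ME1, which encodes malic enzyme, fell among 20 NRF2 and antioxidant genes (-0.32 ± 0.06, limma adjusted p = 0.0440). No other member of these lists passed limma's test over all genes. With an estimated correlation, no list passed in any of the 3 group comparisons. By limma's fry test, which keeps the correlation between genes, cholesterol synthesis, hypoxia and glycolysis and epithelial genes passed with Tip60 siRNA (adjusted p = 0.0458 each). With p400 siRNA, fry passed cholesterol synthesis (0.0155), H2A.Z and other remodellers, double-strand break repair, NRF2 and epithelial genes (0.0219 each). Between Tip60 and p400 it passed repair (0.0211) and NRF2 genes (0.0453). It also passed the complex subunits with p400 siRNA (0.0334) and between Tip60 and p400 (0.0177), a result that the knockdown itself partly fixes, since the list holds KAT5 and EP400. By camera, 14 of the 26 lists passed in none of the comparisons, among them other histone acetyltransferases, interferon-stimulated genes, apoptosis regulators and oxidative phosphorylation (lowest camera adjusted p = 0.152). The median, the mean and the direction of the test differed in sign for 7 lists in the Tip60 comparison, 3 in the p400 comparison and 3 between Tip60 and p400, none of which passed.

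The comparison of p400 siRNA with control siRNA asked the same of p400. GCNT3, which encodes a mucin-type glycosyltransferase, rose 3.05-fold (log2 1.61 ± 0.34, SE, n = 4 against 4; limma adjusted p = 0.0305), and the keratin gene KRT16 rose 2.75-fold (1.46 ± 0.33). SAMD5 (1.45 ± 0.34), TEX19 (1.14 ± 0.22), B3GALT5, a galactosyltransferase gene (1.11 ± 0.26), KLF2 (1.09 ± 0.15) and ANGPT2 (1.08 ± 0.15) rose between 2.12-fold and 2.73-fold. PHOSPHO1, SDR16C5 and EFHD1 rose from 2.25-fold to 2.49-fold, with means below the receptor-gene percentile. Control 2_A, which stood apart, was low for GCNT3 (8.04 against 8.91 to 9.01 in the other controls), which enlarges its rise. The same held for TEX19 (8.23 against 9.28 to 9.42) and SDR16C5 (6.08 against 6.84 to 6.90). Over their alternatives the log2 rises lay between 1.37 and 1.82 (GCNT3), 0.84 and 1.44 (TEX19), and 1.09 and 1.48 (SDR16C5). Apart from EP400, SLC1A3, which encodes a glutamate transporter, had the largest fall among genes above that percentile (-1.08 ± 0.24, limma adjusted p = 0.0386). LCE1E, HOXC8, ROPN1, KLK3, CLEC10A, GPM6A, SLC46A2 and CAPN11 fell from 2.06-fold to 2.63-fold, all with means below it, and 1 of the 2 KLK3 features moved the other way.

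**Figure D2:**
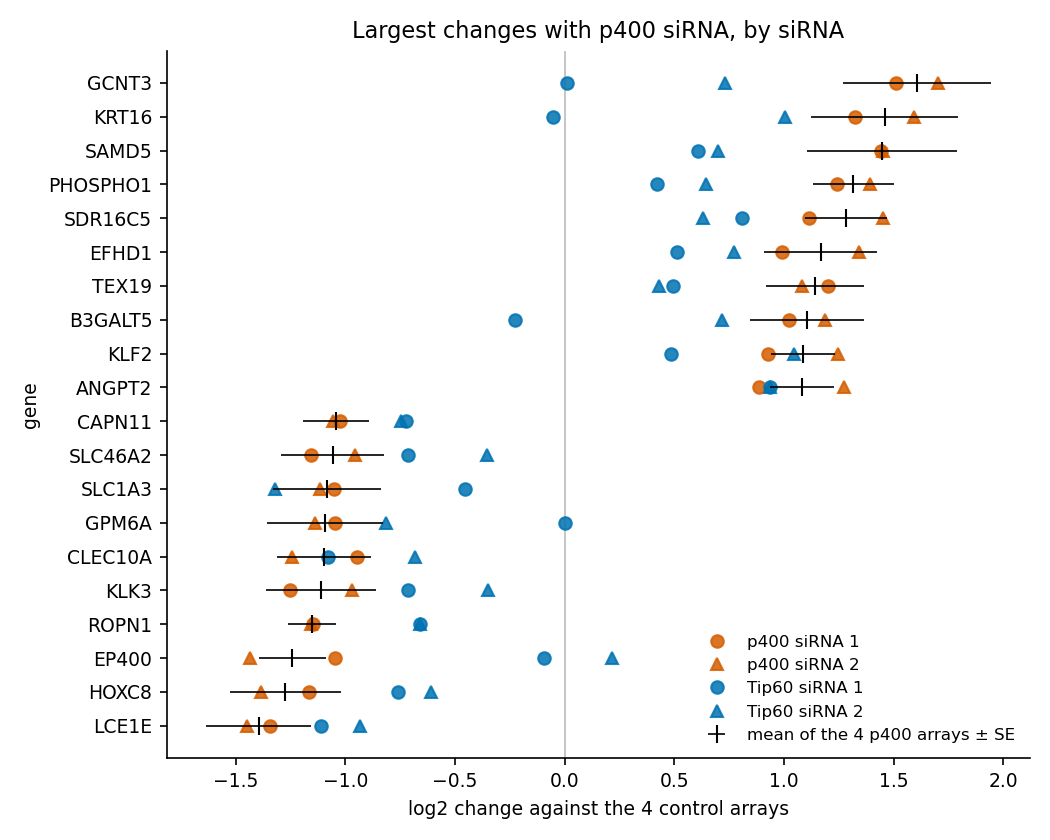
Log2 change against the 4 control arrays (horizontal axis) of the 10 genes with the largest rises and the 10 with the largest falls with p400 siRNA. Orange symbols are the p400 siRNAs and blue symbols the Tip60 siRNAs (circles siRNA 1, triangles siRNA 2, each the mean of 2 arrays), and the black tick is the mean of the 4 p400 arrays with its SE. GCNT3 was 1.51 and 1.70 higher with p400 siRNA 1 and 2, against 0.01 and 0.73 with Tip60 siRNA 1 and 2.

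In total 538 genes passed limma's test, 180 higher and 358 lower with p400 siRNA, and 28 of them changed at least 2-fold, 16 up and 12 down. An unadjusted p under 0.05 was found for 3474 genes. With quantile normalization limma called 509, of which 48.7% were higher instead of 33.5%. Of the 538, 157 also passed with each p400 siRNA alone, a count that was between 0 (without p400 1_A or p400 1_B) and 269 (without Tip60 2_B) when 1 array was left out. Below the receptor-gene percentile lay 53 of the higher and 173 of the lower genes. Without any 1 of the control or p400 arrays the count was between 99 (without p400 2_A) and 349 (without Control 2_A), and without Tip60 2_B it was 836. Without either array that stood apart it was 997, and with siRNA as a random block it was 103.

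Cholesterol synthesis was again the list with the lowest p-value. All 19 measured genes lay lower with p400 siRNA (median -0.29, camera adjusted p = 1.3e-08; adjusted p = 0.474 with an estimated correlation), 5 fell over all genes tested and 15 fell adjusted over the list alone. The 5 were TM7SF2 (-0.29 ± 0.05), SREBF2 (-0.34 ± 0.07), HSD17B7 (-0.44 ± 0.08), ACAT2, a thiolase gene (-0.41 ± 0.07), and EBP, a sterol isomerase gene (-0.36, limma adjusted p = 0.0417). Across the 8 knockdown arrays the mean of the list was 0.25 below that of the 4 control arrays (difference -0.25, exact permutation p = 0.00606 over 495 splits, a test chosen after the result was seen). That test pools both targets and counts the cultures of a siRNA as separate arrays. Against the control arrays alone, the exact permutation p of the list mean was 0.0857 for Tip60 and 0.0286 for p400. Adjusted over the 17 list results past camera's threshold, these were 0.132 and 0.0810, and none of the 17 passed. That adjustment could pass a list only if most of the 17 lay at 0.0286, the smallest exact p, so it decides little. Control 2_A (-0.19) lay within the range of the knockdown arrays, from -0.34 to -0.10. Of 20 NRF2 and antioxidant genes, GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis, rose (0.55 ± 0.09), and 4 rose adjusted over the list alone (median 0.14, camera adjusted p = 0.0109; adjusted p = 0.474 with an estimated correlation). Of 24 Wnt/beta-catenin targets, DKK1 rose (0.32 ± 0.07) and ASCL2, which encodes an intestinal stem cell transcription factor, fell (-0.70 ± 0.16, with a mean below the receptor-gene percentile). Adjusted over the list alone 2 rose and 1 fell (median 0.22, limma camera adjusted p = 0.0179; adjusted p = 0.607 with an estimated correlation). None of 29 p53 targets passed limma's test over all genes or adjusted over the list alone, while the list as a whole lay higher (median 0.11, camera adjusted p = 0.00661; adjusted p = 0.780 with an estimated correlation). Without Control 2_A the p53 list had an adjusted p of 0.144, with a median of 0.05 instead of 0.11, and without p400 2_A the Wnt list had 0.0848. Without control siRNA 2 the p53 list had 0.573, with a median of 0.02 instead of 0.11, and the Wnt list 0.0887. With array weights the p53 list had 0.0900. Without p400 siRNA 1 the p53 list had 0.253, and without p400 siRNA 2 the NRF2 list had 0.0893 and the Wnt list 0.244.

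The other 22 lists had camera adjusted p-values from 0.147 (G2/M genes) to 0.935 (TGF-beta targets and oxidative phosphorylation). Single members of them passed limma's test. Among the 18 TIP60-p400 complex subunits, EPC2 rose (0.49 ± 0.11) and MBTD1 fell (-0.54 ± 0.13, with a mean below the receptor-gene percentile) beside EP400. Adjusted over the list alone, 1 subunit rose and 3 fell. KLF4, an epithelial differentiation factor, rose (0.75 ± 0.16) and VIL1, which encodes the brush border protein villin, fell (-0.59 ± 0.08, mean below the receptor-gene percentile) among 20 intestinal differentiation markers. Of the interferon-stimulated genes, OASL rose (1.04 ± 0.22) and RIGI, an RNA sensor gene, fell (-0.70 ± 0.16, mean below the receptor-gene percentile). The tight junction gene OCLN (-0.36 ± 0.06) and the transcription factor gene GRHL2 (-0.49 ± 0.10) fell among 16 epithelial genes. POLA1, a DNA polymerase gene (-0.47 ± 0.11), the DNA ligase gene LIG1 (-0.29 ± 0.07), NFKB1 (-0.26 ± 0.06), PFKFB4 (-0.45 ± 0.10), the mitochondrial uncoupling protein gene UCP3 (-0.50 ± 0.09) and LAMP2, of which 1 of 2 features moved the other way (-0.39 ± 0.09), also fell. The autophagy gene MAP1LC3B (0.46 ± 0.11) and the cytochrome c oxidase gene COX6C (0.32 ± 0.06) rose. Of the markers of other cell types, CD68, a macrophage marker that also labels lysosomes (0.57 ± 0.11), rose, and CD14 (-0.68 ± 0.17) and COL1A2 (-0.93 ± 0.14) fell, both with means below the receptor-gene percentile.

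**Figure D3:**
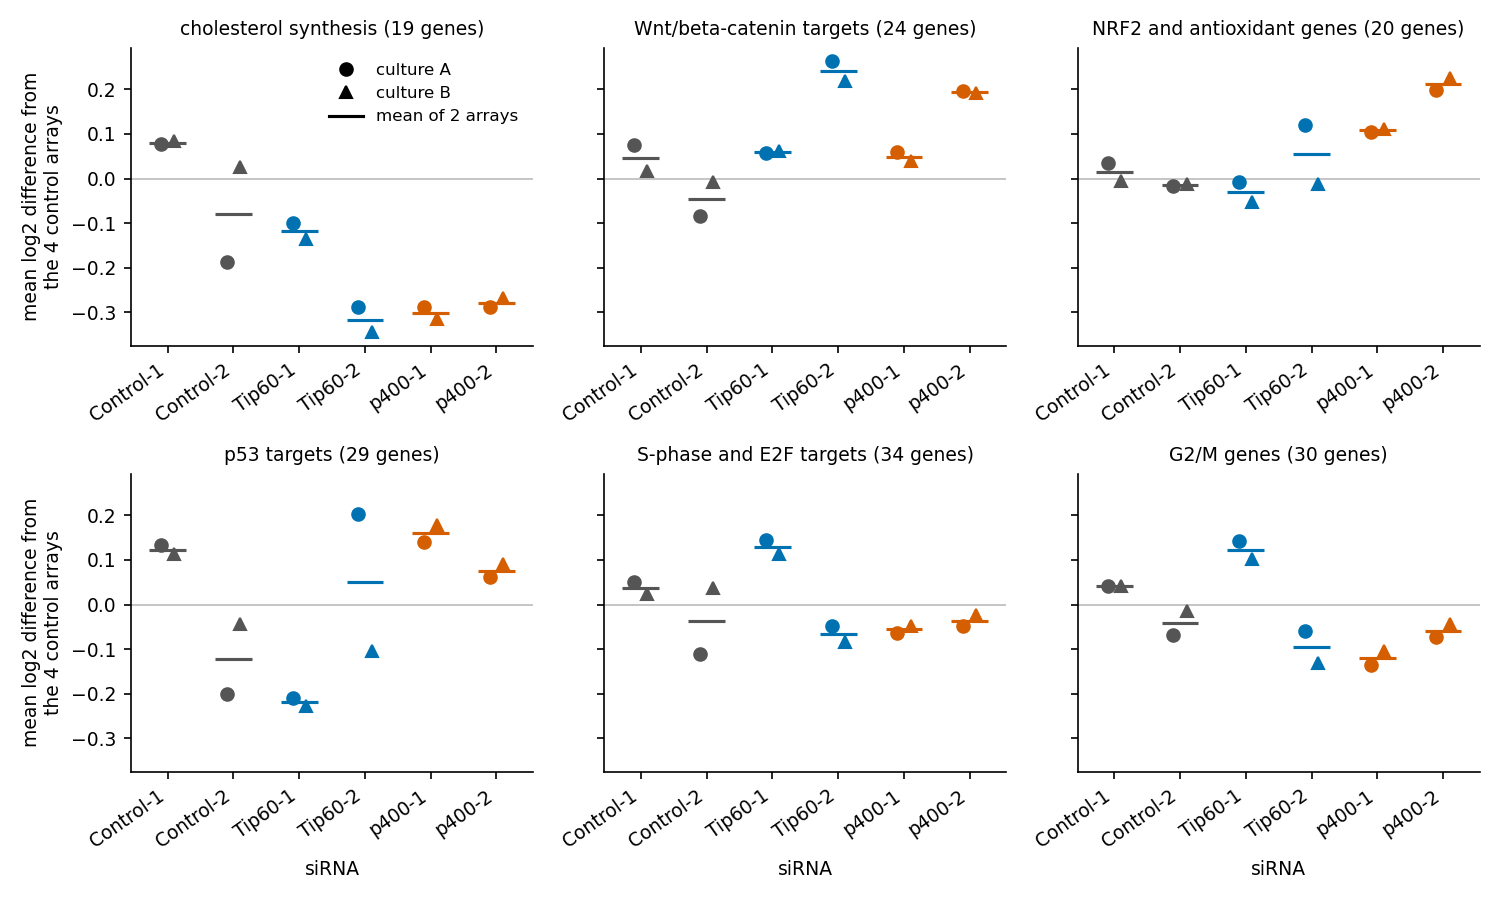
Mean log2 difference of 6 gene lists from the mean of the 4 control arrays (vertical axis), for each of the 12 arrays by siRNA, with circles for culture A, triangles for culture B and a line at the mean of 2 arrays. The cholesterol synthesis list lay between -0.34 and -0.10 in the 8 knockdown arrays, and at -0.19 in Control 2_A.

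The direct comparison of Tip60 with p400 siRNA asked where the knockdowns differed. EP400 was 2.47-fold higher in Tip60 than in p400 cells (log2 1.30 ± 0.15, limma adjusted p = 0.0148), and KAT5 did not pass the test on group means (-1.30 ± 0.32, adjusted p = 0.123). KAT5 passed with 6 siRNA means (limma adjusted p = 0.000162), and its values in the groups did not overlap (exact p = 0.0286). Apart from EP400, the 9 genes with the largest differences higher in Tip60 cells were TEX13B, EDDM3B, ARSF, DYDC2, S100Z, PAQR9, TRIM67, C12orf60 and IL1F10, at most 1.80-fold. PDE2A, PRSS38, JAKMIP2 and PGLYRP4 were lower in Tip60 cells, from 1.41-fold to 1.75-fold. All 13 had means below the receptor-gene percentile, as did VIL1, the other list member that passed (0.54 ± 0.08, limma adjusted p = 0.0400). The test called 20 genes, 16 higher and 4 lower in Tip60 cells, and 2234 had an unadjusted p under 0.05. With the arrays quantile-normalised it called 13, of which 30.8% were higher instead of 80.0%, and with each array centred on its median it called 5, of which 60.0% were higher. It called 167 without Tip60 2_A and 36 without Control 2_A, and 8 or fewer without any 1 of the other arrays except Control 1_A.

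By camera, 8 lists differed between Tip60 and p400 cells. The list of 29 p53 targets as a whole lay lower in Tip60 cells (median -0.19, adjusted p = 8.92e-07; adjusted p = 0.583 with an estimated correlation). The 23 replication-dependent histone genes were all higher (median 0.43, adjusted p = 3.53e-05; adjusted p = 0.583 with an estimated correlation). Set against the control mean, the mean of that list lay between 0.006 (Tip60 2_A) and 0.64 (Tip60 2_B) in the Tip60 arrays. It lay between -0.40 and -0.01 in the p400 arrays, and between -0.61 and 0.32 in the control arrays themselves. By the same limma test, G2/M genes (median 0.09, adjusted p = 0.00380), S-phase and E2F targets (0.07, adjusted p = 0.0181) and double-strand break repair genes (0.11, adjusted p = 0.0167) were higher in Tip60 cells. NRF2 and antioxidant genes (-0.08, limma camera adjusted p = 0.00275), ribosomal proteins (-0.03, adjusted p = 0.0167) and ribosome biogenesis genes (-0.04, adjusted p = 0.0458) were lower. With an estimated correlation the adjusted p of these 6 lists lay between 0.559 and 0.668. No member of the 8 lists passed limma's test over all genes; adjusted over the list alone 1 histone gene and 1 repair gene were higher and 2 NRF2 genes were lower. Without Tip60 siRNA 1 the adjusted p was 0.311 for p53 targets, 0.234 each for NRF2 and repair genes, 0.299 for ribosomal proteins and 0.101 for ribosome biogenesis, and the medians of the S-phase and G2/M lists turned to -0.02. The repair call also ended without Tip60 siRNA 2 (0.0695), without p400 siRNA 1 (0.265) and with centred arrays (0.0578), as the S-phase call did with centred arrays (0.0589) and without p400 siRNA 1 (0.0857). Other calls that ended were G2/M genes without p400 siRNA 1 (0.191), and NRF2 genes and ribosomal proteins without p400 siRNA 2 (0.0623 each). The ribosome biogenesis call ended under 21 of its 31 alternatives (adjusted p from 0.0141 to 0.668). Leaving out 1 array ended the calls of the S-phase list (0.289 without Tip60 1_A, 0.257 without Tip60 1_B, 0.0563 without p400 1_A), the G2/M list (0.140 without Tip60 1_A, 0.0842 without Tip60 1_B), the repair list (0.0690 without Tip60 1_A, 0.0723 without p400 1_A), ribosomal proteins (0.0712 without Tip60 1_A, 0.0676 without Tip60 2_A) and ribosome biogenesis (from 0.0515 without Control 1_B to 0.568 without Tip60 2_B). The S-phase median was then 0.035 without Tip60 1_A or Tip60 1_B, instead of 0.07. The ribosome biogenesis median was -0.008 without Tip60 2_B, instead of -0.04.

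The overlap of the knockdowns was tested next, since both are set against the same control arrays. Of the genes past limma's threshold, 77 were shared by the Tip60 and p400 comparisons in the same direction, 32 higher and 45 lower, and 0 in opposite directions (with 2795 and 3474 genes at an unadjusted p under 0.05). The 5 with the largest shared changes were HLA-DRA (1.10 with Tip60 siRNA and 1.01 with p400 siRNA), ANGPT2 (0.94 and 1.08), KLF2 (0.77 and 1.09), the interleukin receptor gene IL21R (-0.92 and -0.999) and the glucagon receptor gene GCGR (-0.85 and -0.80). Independent lists of these sizes would share 0.792 higher and 1.88 lower genes. Without any 1 of the arrays other than Control 2_A and Tip60 2_B the overlap was between 9 (without Control 2_B) and 35 (without Tip60 1_A), and by limma it was 0 with siRNA as a random block. The log2 changes correlated across genes with r = 0.592 (Spearman 0.566), and genes are not independent replicates. Simulated unchanged groups with the same controls and independent genes gave a mean r of 0.501. Shuffling the residuals of the arrays gave a mean of 0.446. The covariance of the changes was 0.0290 against 0.0133 in the simulated groups, a difference of 0.0157. The spread over the 100 draws is not given here, so the size of these differences cannot be judged. With the controls split between the comparisons, r was between 0.124 and 0.392. The comparisons then shared 0 genes in each of the 4 splits, in which limma called between 0 and 17 genes for Tip60 and between 21 and 132 for p400.

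The last comparison asked whether the 2 siRNAs against a target had the same effect. Between the Tip60 siRNAs 1463 genes differed (745 higher and 718 lower with siRNA 1), 135 of them at least 2-fold, whereas between the control siRNAs limma called 0 genes (1264 with an unadjusted p under 0.05) and between the p400 siRNAs 3. PRF1, which encodes perforin, was at 10.90 with Tip60 siRNA 1 and at 12.90 with siRNA 2 (SE of the log2 difference 0.07, limma adjusted p = 4.39e-05). LYZ, the lysozyme gene, differed by -2.28 ± 0.11, ZNF488 by -1.26 ± 0.07 and B3GNT5, a glycosyltransferase gene, by 1.24 ± 0.08. The 3 genes that differed between the p400 siRNAs were PRF1 (-1.04 ± 0.07), LYZ (-1.45 ± 0.11) and FAM3C (-0.77 ± 0.07). HABP4 and PPIL1 came next and did not pass (limma adjusted p = 0.0568 each), nor did CRYBA2, DUSP10, ZSCAN31, SMAD7 and BTBD3, the genes with the lowest p-values between the control siRNAs (adjusted p from 0.0847 to 0.617).

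With the preset correlation, 4 lists differed between the Tip60 siRNAs, and none did with an estimated correlation. Of 29 p53 targets 6 were lower with siRNA 1 (list median -0.22, limma camera adjusted p = 6.54e-05; adjusted p = 0.977 with an estimated correlation), among them PLK2 (-1.13 ± 0.10), TP53I3 (-0.93 ± 0.08), GDF15 (-0.85 ± 0.10) and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (-0.50 ± 0.11). Of 30 G2/M genes 7 were higher (median 0.22, limma camera adjusted p = 1.11e-06; adjusted p = 0.708 with an estimated correlation), among them the proliferation marker gene MKI67 (0.51 ± 0.07) and CCNB2 (0.49 ± 0.09). Of 34 S-phase and E2F targets 6 were higher (median 0.17, limma camera adjusted p = 2.83e-05; adjusted p = 0.799 with an estimated correlation), among them E2F8 (0.77 ± 0.14) and MCM10 (0.43 ± 0.07). Of 19 cholesterol synthesis genes 4 were higher (median 0.19, limma camera adjusted p = 0.0283; adjusted p = 0.977 with an estimated correlation), among them STARD4 (0.80 ± 0.20) and SQLE (0.53 ± 0.11). These members were chosen after their values were seen. Between the p400 siRNAs, 5 lists passed with 0 called members each (limma; 1178 of all genes with an unadjusted p under 0.05): p53 targets (median 0.12, adjusted p = 0.0307), Wnt/beta-catenin targets (-0.12, 0.0186), G2/M genes (-0.04, 0.0307), oxidative phosphorylation (0.04, 0.0214) and mesenchymal and fibroblast markers (-0.08, 0.0311). With an estimated correlation none of these 5 passed (adjusted p at least 0.513).

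**Figure D4:**
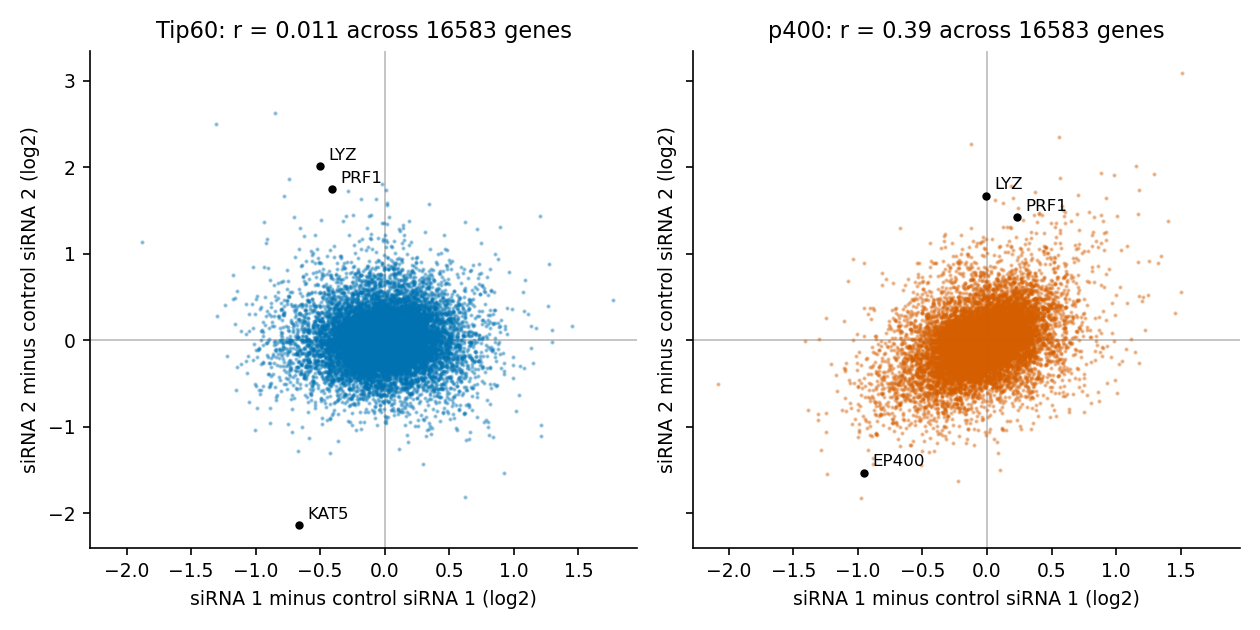
Log2 change with siRNA 2 (vertical axis) against siRNA 1 (horizontal axis) for each of 16583 genes, each siRNA set against the control siRNA of its own number, for Tip60 (left) and p400 (right). The changes correlated with r = 0.011 for Tip60 and r = 0.39 for p400, and KAT5, EP400, LYZ and PRF1 are marked.

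Set against separate control siRNAs, the changes with the siRNAs of a target correlated across genes with r = 0.011 (Spearman 0.050) for Tip60 and r = 0.393 (Spearman 0.363) for p400. Taken alone against both control siRNAs, Tip60 siRNA 1 changed 468 genes and Tip60 siRNA 2 changed 1437, of which 106 were shared in the same direction (20.5 for independent lists) and 37 in opposite directions. With separate control siRNAs they shared 13 in the same direction and 21 in opposite directions, or 13 and 10 with the control siRNAs exchanged. For p400 the numbers were 360 and 1088, with 238 shared in the same direction (12.2 for independent lists) and 0 in opposite directions, and 56 and 3, or 61 and 0, with separate control siRNAs. NECTIN4, ZNF488, SERPINB1 and PPL fell with Tip60 siRNA 1 and rose with siRNA 2, and SLC4A7 and B3GNT5 did the reverse, chosen after their values were seen. The number of genes that differed between the Tip60 siRNAs ranged from 244 without Tip60 1_A to 2069 without Tip60 2_A.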

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

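The 7 counts over other splits of the arrays were planned before the data were examined; the tests of the 3 patterns weighed here, the resemblance of the siRNAs, the arrays that stood apart and cholesterol synthesis, were chosen after the result was seen.

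A test of the difference between siRNAs of a target called 1463 genes and 4 gene lists between Tip60 siRNA 1 and siRNA 2, and 3 genes and 5 gene lists between the p400 siRNAs.

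The first pattern is that the Tip60 siRNAs changed different genes, and that Tip60 siRNA 2 resembled p400 siRNA (r = 0.272, each against other control arrays) more than siRNA 1 did (0.0823). Against a graded effect of the remaining KAT5 transcript as the whole cause, 37 genes passed with both Tip60 siRNAs in opposite directions. An array or hybridisation batch shared by the Tip60 siRNA 2 and p400 arrays was tested on receptor genes near the background. The correlation across them was -0.207 (bootstrap interval over genes -0.307 to -0.111), and 0.453 across 7605 genes with a mean above 10. These values cannot decide about a batch. Tip60 2_B and the control array Control 2_A deviated together across receptor genes (r = 0.790), which can lower the correlation there, and the bootstrap over genes does not cover that. A transfection or culture day shared by the Tip60 siRNA 2 and p400 cultures could give the correlation of 0.453, and cannot be told apart from a shared function of Tip60 and p400, because the labels give no days. An unintended target of 1 of the Tip60 siRNAs could give the correlation of 0.0112 between them, and cannot be told apart from other differences between these siRNAs, because the siRNA sequences were not used here.

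The second pattern is that Control 2_A and Tip60 2_B stood apart. Tip60 2_B lay at -40.7 on the first principal component, far from the other Tip60 arrays (5.03 to 6.32), and Control 2_A at -30.1. Families of similar genes were low in both: the 14 KIR genes by a mean of -1.30 in Control 2_A and -1.52 in Tip60 2_B, and the 10 PSG genes by -1.49 and -1.26. Against an exchange of the 2 samples, KAT5 was 2.24 higher (log2) in Control 2_A than in Tip60 2_B (12.59 against 10.35), in keeping with their labels. The same families were highest in Control 1_A (KIR 0.94, PSG 0.89). Hybridisation on single arrays is a candidate explanation. The deviations of the 2 arrays correlated with r = 0.790 across receptor genes and 0.656 across genes with a mean above 10. That test does not separate hybridisation from carried-over DNA. DNA added to these 2 arrays alone would not lower the families in them. No biological explanation was tested.

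The third pattern is the lower level of cholesterol synthesis genes with both knockdowns. Chance in the shared control arrays cannot be told apart from an effect on the list: its highest median with the controls split between the comparisons was -0.130, and its mean varied between the control arrays with an SD of 0.13, too much for 2 control arrays per comparison to decide. Against 1 control array as the cause of the call with the preset correlation, the highest camera adjusted p without any 1 control array was 1.99e-05. It speaks to that call only. With an estimated correlation the list passed in neither comparison (camera adjusted p = 0.406 for Tip60 and 0.474 for p400), with all arrays kept. A difference in cell density or medium between transfections could shift the list by the measured -0.253 (8 against 4 arrays). It cannot be told apart from an effect of Tip60 and p400, because the labels give neither density nor the time of feeding for each culture. The exact permutation p was 0.0857 for Tip60 and 0.0286 for p400 alone. Adjusted over the 17 list results past camera's threshold, these were 0.132 and 0.0810. That adjustment could pass a list only if most of the 17 lay at 0.0286, the smallest exact p.

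Single arrays far from the other 3 of their group were found in 20 of 321 groups tested (6.23%), and chance flags about 1 in 20 groups. Control 2_A was the array in 5 of them. They were its mean of S-phase and E2F targets (-0.11 against the controls), CERKL (5.38), GCNT3 (8.04), SDR16C5 (6.08) and TEX19 (8.23). The others were HTR1E (5.96) and PGLYRP4 (6.99) in Control 1_A, CD14 (5.88) in Control 1_B, CFHR2 (5.43) and CLEC10A (6.29) in Tip60 1_A, and HLA-DRA (7.95) and NFKB1 (12.65) in Tip60 1_B. GCNT3 (10.27) and HSD17B7 (10.45) stood apart in Tip60 2_A, CLEC10A (7.08) and ARSF (4.82) in p400 1_A, P4HA1 (10.68) in p400 2_A, and MBTD1 (5.79) and POLA1 (11.24) in p400 2_B.

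The 26845 features without a gene symbol, outside the main measurement, were tested in the same way. Limma called 220 of them with Tip60 siRNA (126 higher, 94 lower), 750 with p400 siRNA (212 higher, 538 lower) and 148 between Tip60 and p400 (123 higher, 25 lower).

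Other splits of the same 8 arrays into 4 and 4 were tested as well. For genes, the real split gave the highest count in each comparison, 1 of 35 splits, the smallest share this design can give. For p400 the real split gave 538 genes (103 with siRNA as a random block), and the highest other gave 0. For p400 that share argues against chance between arrays. It cannot exclude chance between siRNAs, because the splits count cultures of 1 siRNA as separate. Tip60 gave 160 genes (highest other 129), and Tip60 against p400 gave 20 (highest other 19). With siRNA as a random block limma called 0 in both (2002 and 1507 at an unadjusted p under 0.05), so that chance is left open for both. The split with 129 genes exchanged Control 2_A with Tip60 2_A, and the split with 19 set both siRNAs 1 against both siRNAs 2. For the 77 genes shared by the knockdowns, 1 of 100 drawn splits gave as many, the real one, and the highest other gave 0. None of the other 99 called genes in both comparisons, so that their overlap was 0 by construction and this test decides nothing about chance. For gene lists chance cannot be excluded: 9 of 35 splits gave as many as the real 5 for Tip60 (highest other 6), 10 gave as many as the real 4 for p400 (highest other 6), and 2 gave as many as the real 8 between Tip60 and p400 (highest other 9).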

How the results depend on the processing

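The alternatives were planned before the data were examined, except leaving out Control 2_A and Tip60 2_B together, which was chosen after the result was seen. Where a value below changed, the cause was not tested, unless fewer arrays or a stricter threshold made it so by construction.

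The number of genes changed with Tip60 siRNA (160) was 390 with every feature on its own, 671 with array weights and 646 with 6 siRNA means. With only the 2 groups compared limma called 0 (2109 at an unadjusted p under 0.05), and with siRNA as a random block 0 (2002). It was 10 and 0 without control siRNA 1 and 2, 1104 and 633 without Tip60 siRNA 1 and 2, and 11 and 0 without p400 siRNA 1 and 2. A log2 change of at least 1 left 1 gene. It was 223 with centred arrays, of which 29.6% were higher instead of 45.6%. Without 1 array it ranged from 14 (without Control 2_B) to 163 (without Control 2_A).

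The number changed with p400 siRNA (538) was 1350 with every feature, 3459 with array weights, 1559 with the 2 groups compared, 1602 with 6 siRNA means and 103 with siRNA as a random block. It was 33 and 8 without control siRNA 1 and 2, 1380 and 1787 without Tip60 siRNA 1 and 2, and 15 and 0 without p400 siRNA 1 and 2. A log2 change of at least 1 left 28 genes. Without Control 2_A and Tip60 2_B it was 997, and without 1 array it ranged from 99 (without p400 2_A) to 836 (without Tip60 2_B). Quantile normalization gave 509, of which 48.7% were higher instead of 33.5%.

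Between Tip60 and p400 (20 genes) the count was 5 with centred arrays, 13 with quantile normalization, 1 without the lowest 30% of genes, 159 with every feature, 2 with trended and robust moderation, 1217 with array weights and 286 with 6 siRNA means. It was 0 with the 2 groups compared and 0 with siRNA as a random block. It was 5 and 4 without control siRNA 1 and 2, 2 and 1524 without Tip60 siRNA 1 and 2, and 0 and 0 without p400 siRNA 1 and 2. A log2 change of at least 1 left 1 gene, and 36 were called without Control 2_A and Tip60 2_B. Without 1 array it ranged from 0 (without p400 2_A) to 167 (without Tip60 2_A).

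The overlap of the knockdowns (77 genes) was 173 with every feature, 372 with array weights, 357 with 6 siRNA means, 0 with the 2 groups compared and 0 with siRNA as a random block. It was 7 and 0 without control siRNA 1 and 2, 506 and 156 without Tip60 siRNA 1 and 2, 1 and 0 without p400 siRNA 1 and 2, 1 with a log2 change of at least 1 and 122 without Control 2_A and Tip60 2_B. With the controls split between the comparisons it was 0 in each of the 4 splits by limma. Without 1 array it ranged from 9 (without Control 2_B) to 76 (without Tip60 2_B).

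A block for the culture letter gave 40 genes for Tip60, 305 for p400, 4 between them and an overlap of 22. A block for the whole replicate label gave 4, 173, 0 and 4. The numbers do not show a pairing: of 12 pairs of arrays with the same label in different groups, 2 had deviations that correlated above 0.1, and the range was -0.470 to 0.234. The letter block also gave 824 genes between the Tip60 siRNAs, and 11 and 41 genes that passed with each siRNA of Tip60 and of p400.

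KAT5 passed the threshold with array weights (log2 change -0.98), with 6 siRNA means (-1.40), without Tip60 siRNA 1 (-2.15), without Tip60 siRNA 2 (-0.65) and without Tip60 1_A (-1.66, limma adjusted p = 0.0498; range over its alternatives 5.52e-06 to 0.248). Without 1 array its change ranged from -1.66 to -1.12. EP400 missed the threshold without control siRNA 2 (-1.15) and without p400 siRNA 2 (-1.05), and ranged from -1.32 to -1.13 without 1 array.

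Of the gene lists, 3 instead of 5 passed for Tip60 with array weights, 3 without control siRNA 1, 2 without Tip60 siRNA 1 and 3 without Control 2_A and Tip60 2_B (2 to 6 without 1 array). For p400 the range without 1 array was 3 to 5, around the real 4. Between Tip60 and p400, 1 instead of 8 passed without Tip60 siRNA 1 and 4 without p400 siRNA 1 (3 to 8 without 1 array). With an estimated correlation 0 lists passed in each comparison. Of the named genes and lists, 3 turned their direction. Without Tip60 siRNA 1 the median between Tip60 and p400 was -0.019 for S-phase and E2F targets and -0.015 for G2/M genes. EP400 with Tip60 siRNA, which passed under none of its alternatives, turned from 0.06 to -0.033 without control siRNA 1, -0.094 without Tip60 siRNA 2, -0.016 without Control 1_B and -0.017 without Tip60 2_B. Without 1 array it ranged from -0.017 to 0.174 (without Control 2_A).

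Between the control siRNAs limma called 0 genes under every alternative (1264 at an unadjusted p under 0.05 in the planned fit). Between the Tip60 siRNAs (1463) it called 2582 with every feature, 650 with array weights and 135 with a log2 change of at least 1, and from 244 to 2069 without 1 array. Between the p400 siRNAs (3) it called 8 with quantile normalization, 17 without the lowest 30% of genes, 11 with every feature, 13 with trended and robust moderation, 595 with array weights and 13 without Control 2_A and Tip60 2_B, and from 0 to 5 without 1 array.

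The genes that passed with each Tip60 siRNA (81) were 134 with centred arrays, 123 without the lowest 30% of genes, 147 with every feature, 6 with array weights and 1 with a log2 change of at least 1, and from 0 to 43 without 1 array. Those of p400 (157) were 248 without the lowest 30% of genes, 317 with every feature, 238 with trended and robust moderation, 812 with array weights, 14 with a log2 change of at least 1 and 430 without Control 2_A and Tip60 2_B, and from 0 to 269 without 1 array. The correlation of the siRNAs ranged from -0.060 to 0.072 for Tip60 and from 0.251 to 0.476 for p400 without 1 array.

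For the 162 named genes and 17 lists, 5358 values were recomputed under the alternatives that apply to each. Of these 3924 kept their direction and their side of the threshold, 1337 no longer passed it, 91 passed it only under the alternative and 6 turned. Leaving out the lowest 30% of genes kept 11608. The level over background limits the rest: genes below the receptor-gene percentile of 7.72 made up 5996 of 16583.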

Other observations

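The genes below were chosen after the result was seen, and so were the comparisons of single siRNAs across targets.

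Tip60 siRNA 2 and p400 siRNA 2, each against both control siRNAs, changed 615 genes in the same direction and 0 in opposite directions by limma (1437 and 1088 genes passed). Independent lists of these sizes would share 47.4. With separate control siRNAs they shared 224 genes in the same direction and 2 in opposite directions, or 182 and 0 with the control siRNAs exchanged. Tip60 siRNA 1 and p400 siRNA 1 shared 46 in the same direction and 10 in opposite directions, and 5 and 4, or 3 and 3, with separate controls. Tip60 siRNA 2 and p400 siRNA 1 shared 184 in the same direction and 1 in opposite directions (57 and 1, or 45 and 1, with separate controls). Tip60 siRNA 1 and p400 siRNA 2 shared 94 and 24 (11 and 17, or 8 and 4, with separate controls).

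Of the genes shared by Tip60 siRNA 2 and p400 siRNA 2, KRT13, a keratin gene, rose by 2.18 and 2.76 (log2), LCN2, which encodes lipocalin 2, by 2.47 and 1.85, and the lysozyme gene LYZ by 1.89 and 1.56. The placental alkaline phosphatase gene ALPP rose by 1.53 with each, and CHI3L1, a chitinase-like gene, by 1.46 and 1.61. With Tip60 siRNA 1 their log2 changes were -0.98, -0.69, -0.38, -0.22 and -0.01, and none of the 5 passed limma's test. With p400 siRNA 1, KRT13 (1.84) and LCN2 (1.31) passed, and LYZ (0.11), ALPP (0.73) and CHI3L1 (0.37) did not.

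All 4 siRNAs changed 27 genes in the same direction, 12 higher and 15 lower, each against the mean of both control siRNAs. With Tip60 siRNA 1, Tip60 siRNA 2, p400 siRNA 1 and p400 siRNA 2, the monoamine oxidase gene MAOB rose by 0.60, 0.61, 0.78 and 0.87 and REEP1, which shapes the endoplasmic reticulum, by 0.62, 0.58, 0.72 and 0.76. CRYZ changed by -0.51, -0.87, -0.46 and -0.73, and AJUBA, which encodes a LIM domain scaffold protein, by -0.45, -0.57, -0.62 and -0.68. These counts share the control arrays.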
